A study of Rattus norvegicus with 2 samples.

How the data were processed

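Total RNA was extracted from splenic NK cells of PVG.7b rats that had been depleted of other cells with antibodies to the alpha-beta T cell receptor, CD68, CD5, immunoglobulin kappa chain and CD45RA, and then sorted as CD3-negative, NKR-P1A-positive cells carrying either NKR-P1B or Ly49s3, per the labels. Biotinylated cRNA was made from 3 ug of total RNA and hybridised to Affymetrix rat arrays, 1 per population, per the labels. How the RNA of the 9 rats was divided or pooled is not given in the sources used here.

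The deposited values are microarray intensity values on a linear scale, 1 per probe set and array, computed with MAS5 per the submitters' processing notes. MAS5 in general combines the perfect-match and mismatch probes of a probe set into 1 signal and can scale each array by a factor. Its version, scaling target and detection calls are not given in the sources used here. The values ranged from 0 to 6639 on the NKR-P1B+ array and from 0 to 6622 on the Ly49s3+ array, with medians of 19.6 and 21.3. The mean after trimming 2% at each end was 100.04 on both arrays, so the scale is linear with a common trimmed mean, the genes were not centred, and the direction of the difference follows from the 2 arrays themselves. The scaling factor applied before stays unknown. The 3' to 5' signal ratio of the actin control probe sets was 11.9 on the NKR-P1B+ array and 13.2 on the Ly49s3+ array, and that of Gapdh 2.84 and 2.77. Signal toward the 5' end of these controls was thus lower on both arrays, and its effect on other probe sets was not tested. No per-sample column was left unused.

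Probe sets were named from the platform annotation supplied with the values. Of 31099 probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none listed, 9780 of the latter without the controls. The symbols were compared by gene number with a RefSeq table of the GRCr8 assembly, which held the genes of 20764 probe sets and changed 0 symbols. That assembly was used for names only and no coordinates are given, since no build is named for the array. Probe sets with several genes were left out of gene results and named as such where their values are given. Some genes are not analysed here because no probe set carried their symbol alone, Ly49s3 among them.

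Values were used on the deposited scale, floored at 20.4, the 50th percentile of all non-control values of both arrays pooled, and converted to log2. A gene was represented by its probe set with the highest mean log2 signal, and was measured if at least 1 array was above the floor, which held for 9114 of 14217 genes, 8286 of them above it on both. The difference is NKR-P1B+ minus Ly49s3+, and genes at least 2-fold apart were counted. A ratio with a value at the floor is a lower bound, and the floor entered the list medians in the same way. With 1 array per population there are no residual degrees of freedom, so no p-value was computed. Precision was described by the spiked controls and by the disagreement of probe sets of the same gene, as the SD of the difference between 2 probe sets divided by the square root of 2, within ranges of mean signal. Probe sets of a gene share the RNA, the sort and the arrays, so this spread leaves out variation between rats, sorts and arrays.

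Before the data were examined, 32 gene lists were fixed, 9 of them markers of other cell types, along with the design, the rule for named genes and the other settings to be tried. The lists cover Ly49 receptors, NKR-P1 receptors and Clr ligands, CD94/NKG2 and other lectins, activating receptors, cytotoxic genes, cytokines, cytokine receptors, homing genes, transcription factors, late-maturation, early-maturation and tissue-resident genes, activation, immediate early, proliferation, interferon-stimulated, apoptosis, receptor-proximal signalling, glycolysis, cholesterol synthesis, MHC class I, ribosomal protein and oxidative phosphorylation genes. The marker lists cover antigen-presenting cells, B cells, plasma cells, T cells, macrophages, neutrophils and mast cells, erythroid cells, platelets and stroma. For each list the median difference over measured members was set against 10000 random lists of the same size, drawn from all measured genes within 20 bins of mean signal, and members at least 1.5-fold apart were counted. The percentile describes these 2 arrays and is no test between cell populations.

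The rule named, per direction, the 12 genes with the largest difference among those above the floor on both arrays and the 4 brightest genes above it on 1 array only with a bound of at least 2-fold. It also named every measured gene of the 3 NK gene complex lists, up to 3 members per direction of each other list at least 1.5-fold apart, and the 2 brightest members of each marker list, in all 121 genes. Symbols of unnamed transcripts were counted but not named.

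The other settings fixed beforehand were centring on the median, quantile normalisation, subtraction of a loess trend with a span of 0.3, floors at the 35th and 65th percentiles, log2 of the value plus 32 without a floor, the mean over probe sets of a gene, leaving out probe sets that can match several transcripts, and thresholds of 1.5-fold and 3-fold. Alternatives added after seeing the data were a floor at 100, scaling to the poly-A spikes, list medians over members with a mean signal of at least 100 for the proliferation and T cell lists, and inclusion of the Ly49 probe sets that match several genes. A further 7 gene families were defined after the data were seen.

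The calculation was tested on simulated data built from these 2 arrays, with 8938 genes in the step. The 2-fold count took in 6% of 50 genes made 1.5-fold apart, 58% of 50 made 2-fold apart, and 100% of 50 made 3-fold and of 50 made 4-fold apart. It took in 10 of 8738 unchanged genes. The simulated noise was set near the spread between probe sets and held no variation between rats or sorts. Changes were given only to genes well above the floor, so these shares are not error rates of the real count. Of 100 simulated lists of 16 genes without a shift 5 fell outside the central 95% of random lists, and of 100 shifted by 0.4 on the log2 scale all 100 did. The shift was added to each median itself, which largely fixed that outcome. The simulated lists held genes drawn at random, so they do not show how lists of genes regulated together vary. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.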

Results

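Gene expression was measured in 2 populations of natural killer (NK) cells sorted from rat spleen. NK cells are lymphocytes that kill infected or altered cells, and each carries a varied set of lectin-like receptors encoded in the NK gene complex. Sorted cells carried NKR-P1A, lacked CD3, and were positive either for NKR-P1B or for Ly49s3 but not for both. NKR-P1B is an inhibitory receptor of the NKR-P1 family and Ly49s3 is an activating receptor of the Ly49 family. Per the labels, 9 PVG.7b rats aged 8 to 12 weeks were used and the sorted cells were above 90% pure. Each population was hybridised to 1 expression array with 31099 probe sets, so there are no replicates, no test was possible and every difference below describes these 2 arrays. Signal is in arbitrary units, with medians of 19.6 on the NKR-P1B+ array and 21.3 on the Ly49s3+ array. Across the 14565 probe sets above the floor of 20.4 on both arrays, log2 signals correlated with Pearson's r of 0.973, a correlation across probe sets that are not independent replicates. The number of arrays limits the precision.

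The comparison asked how the transcripts of NKR-P1B+ and Ly49s3+ NK cells differ. The NKR-P1B+ array had higher signals of the death receptor gene Tnfrsf25, the death ligand genes Faslg and Tnfsf10, the cytokine genes Il4, Tnf and Ltb, the transcription factor gene Rora, and the NKG2 receptor genes Klrc1 and Klrc2. The Ly49s3+ array had higher signals of the lectin-like receptor gene Klrh1, the growth factor gene Vegfc and 45 of 52 proliferation genes. All 4 measured Ly49 genes were higher there too, but their probe sets may read the sorted receptor. On the deposited scale 19 of 22 cytotoxic granule and death ligand genes and all 31 receptor-proximal signalling genes were within 1.5-fold. So were most of all 9114 measured genes. Of these, 466 were at least 1.5-fold higher on the NKR-P1B+ array and 522 on the Ly49s3+ array. Of 9114 measured genes, 162 were at least 2-fold higher on the NKR-P1B+ array and 110 on the Ly49s3+ array, together 2.98%. The median log2 difference, NKR-P1B+ minus Ly49s3+, was −0.02 with an SD of 0.42 across genes. A signal at or below the floor was set to the floor before a ratio was taken, so such a ratio is a lower bound and is written as "at least". Floors at the 35th and 65th percentiles of all signals, or log2 of the value plus 32 in place of a floor, gave from 77 to 274 and from 37 to 298 such genes. Scaling the arrays to their poly-A spikes, tried after the data were seen, gave 713 and 35, and moved the proliferation median of −0.41 to 0.017. The median over genes above the floor on both arrays was then 0.51, so the proliferation median stayed below it. This scaling also gave medians of 0.56 for the cytotoxic and 0.55 for the receptor-proximal genes. List directions and the counts of members within 1.5-fold are therefore relative to the deposited scale. Of the counted genes, 33 higher on the NKR-P1B+ array and 35 higher on the Ly49s3+ array are such bounds.

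**Figure D1:**
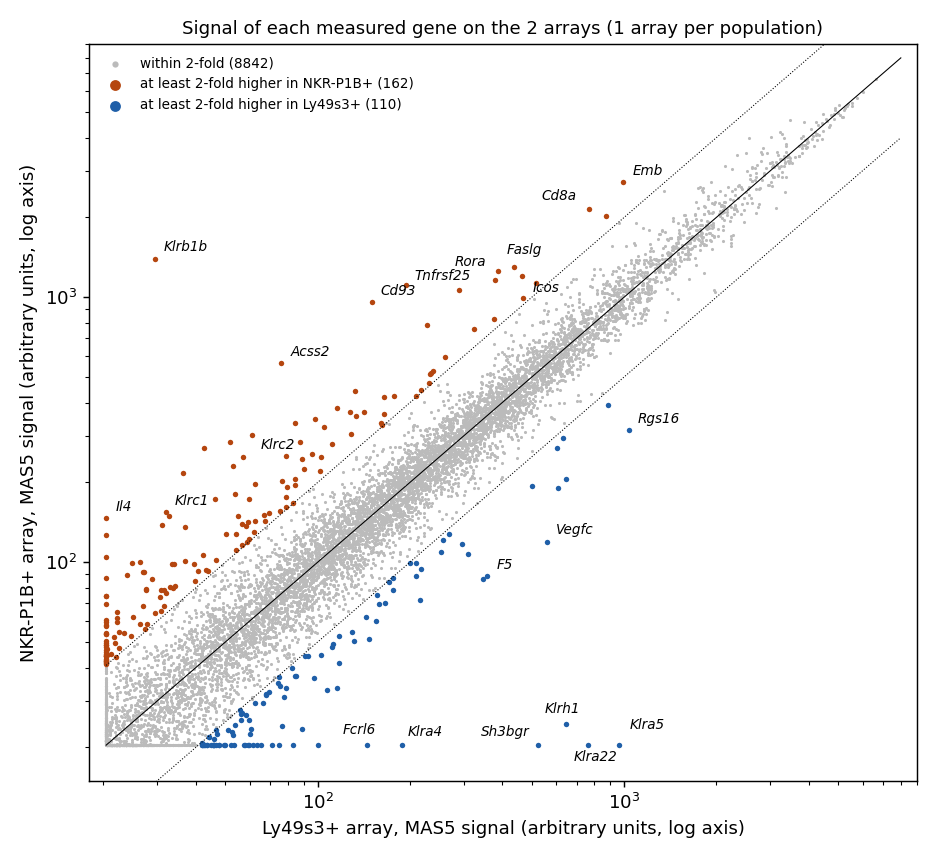
Signal of each of the 9114 measured genes on the Ly49s3+ array (horizontal, log axis) and the NKR-P1B+ array (vertical, log axis), in arbitrary units with values below the floor of 20.4 drawn at the floor; the solid line marks equal signal and the dotted lines a 2-fold difference. The 162 genes at least 2-fold higher on the NKR-P1B+ array and the 110 higher on the Ly49s3+ array are coloured, on the deposited scale.

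The receptors used for the sort were examined as a check of the labels and are no finding. Klrb1b, which encodes NKR-P1B, had a signal of 1399 on the NKR-P1B+ array and 29.4 on the Ly49s3+ array, a 47.6-fold difference. No probe set was annotated with Ly49s3 alone. A probe set matching 7 Ly49 genes had 43.1 on the NKR-P1B+ array and 1720 on the Ly49s3+ array, 39.9-fold higher in the latter, and another matching 4 Ly49 genes was at least 21.7-fold higher there, at 442 against 10.3. Klrb1a, which encodes the NKR-P1A by which all cells were sorted, had 3740 and 3813. On each array the signal of the sorted receptor, or of its family, was the higher one.

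The 4 measured Ly49 genes were all higher on the Ly49s3+ array. Klra5 was at least 47.2-fold higher (962.5 against 7.5), Klra22 at least 37.5-fold (764 against 13.9), Klra4 at least 9.25-fold (189 against 18.1) and Ly49s7 at least 2.90-fold (59.2 against 0.4). Their median log2 difference, with values at the floor, was −4.22, below all 10000 random gene lists of the same size and mean signal. Some Ly49 genes are similar enough to share a probe set. A probe set can thus take signal from several of them, and the assignment to single genes is uncertain. Signal of the sorted Ly49s3 could therefore give this direction, and the percentile is no support for a difference in other Ly49 genes. Klrh1, another lectin-like receptor of the complex, was 26.4-fold higher on the Ly49s3+ array (647.5 against 24.5) and Klre1 was 1.59-fold higher (96.0 against 60.2). Klrc1 and Klrc2, which encode NKG2 chains that pair with CD94, were higher on the NKR-P1B+ array by 4.84-fold (154 against 31.9) and 4.96-fold (302 against 60.9), and are similar enough to share signal. Klrd1, which encodes CD94, had 3149 and 3151, and Klrk1, which encodes NKG2D, had 875 and 908. Klrg1 had 272 and 241, and Cd69 had 4586 and 4244. The 8 measured genes of this CD94/NKG2 group had a median difference of 0.06 and a mean of −0.07, opposite in sign, with Klrh1 at −4.72 against 2.27 and 2.31 for Klrc1 and Klrc2. The 5 measured NKR-P1 and Clr genes had a median of −0.03, at the 47.8th percentile of random lists, and a mean of 1.22 set by Klrb1b. Among them Klrb1c had 1845 and 1944, Clec2d2l2 was 1.88-fold higher on the NKR-P1B+ array (53.4 against 28.4), and Clec2l had 20.3 and 25.1.

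**Figure D2:**
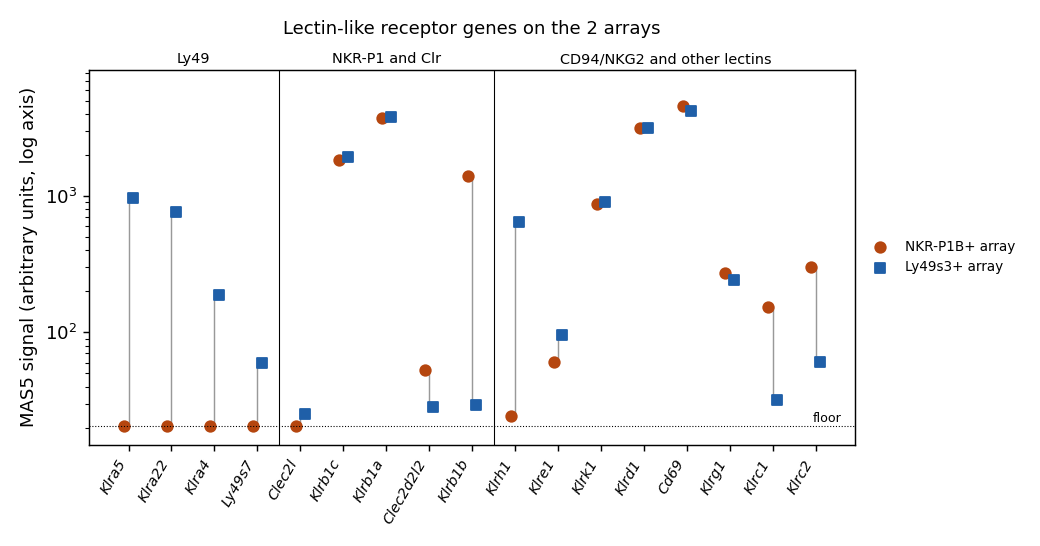
Signal of the measured NK gene complex receptor genes on the NKR-P1B+ and the Ly49s3+ array (arbitrary units, log axis; 1 array per population, so no error bars; values below the floor of 20.4 are shown at the floor). Klrb1b, Klrc1 and Klrc2 were higher on the NKR-P1B+ array and the Ly49 genes and Klrh1 on the Ly49s3+ array, while Klrd1, Klrk1 and Klrb1a lay close together.

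Outside the receptor complex, among named genes above the floor on both arrays, the largest difference toward the NKR-P1B+ array was that of Acss2, the cytosolic enzyme that makes acetyl-CoA from acetate, which was 7.40-fold higher (563 against 76.1). Cd93, a membrane glycoprotein of myeloid and endothelial cells and some lymphocytes, was 6.37-fold higher (958 against 150.3), although its other probe set gave a log2 difference of 0.15 against 2.67. Tnfrsf25, a receptor of the TNF family, was 5.73-fold higher (1108 against 193.5), and Lpar1, a receptor for lysophosphatidic acid, 5.96-fold (216 against 36.3). The secreted glycoprotein gene Olfm1 was 6.35-fold higher (269.9 against 42.5) and Ankrd6 5.48-fold (284 against 51.8). Their probe sets disagreed, with a lowest log2 difference of 0.38 for Olfm1 and 0.53 for Ankrd6. Prrt1 was 4.56-fold higher (149.6 against 32.8), the progranulin gene Grn 4.45-fold (138 against 31.1) and the integrin gene Itgb3 4.39-fold (250.0 against 57.0). Of genes below the floor on the Ly49s3+ array, Il4 was at least 7.18-fold higher (146 against 3.2), Efhd1 at least 6.22-fold (127 against 11.0), the desmoplakin gene Dsp at least 5.11-fold (104 against 16.6) and Tnf at least 4.29-fold (87.5 against 8.7).

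Toward the Ly49s3+ array, the lymphatic growth factor gene Vegfc was 4.69-fold higher (561 against 119.7). The coagulation factor gene F5 was 4.04-fold higher (358 against 88.6) and Trat1, an adaptor of antigen receptors, 4.02-fold (346 against 86.2). Rgs16, which shortens G protein signals, was 3.28-fold higher (1037 against 316), Slc25a4, a mitochondrial carrier of ADP and ATP, 3.20-fold (610.5 against 190.6) and Rasl11b 3.15-fold (649 against 206). The transcriptional repressor gene Gfi1 was 2.99-fold higher (216 against 72.3), with a log2 difference of −1.58 on that probe set and −0.50 on its other. Lower signals were involved for the deubiquitinase gene Usp44 (3.26-fold, 107 against 32.8), the immunoglobulin variable gene Ighvl1 (3.45-fold, 116 against 33.5) and the muscle genes Tnni2 (3.79-fold, 88.6 against 23.4) and Myh2 (3.18-fold, 76.4 against 24.0). Sh3bgr was below the floor on the NKR-P1B+ array and at least 25.7-fold higher on the Ly49s3+ array (524.5 against 12.1).

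The cytotoxic granule and death ligand genes had a median difference of 0.03 over 22 measured members, at the 68.7th percentile of random lists. The 3 members at least 1.5-fold apart were all higher on the NKR-P1B+ array, namely Tnfsf10, which encodes the death ligand TRAIL (3.33-fold, 441 against 132.5), Faslg, which encodes Fas ligand (2.99-fold, 1304 against 436.5), and the granzyme gene Gzmb (1.56-fold, 3973 against 2549). Of 14 activating and immunoglobulin-like receptor and adaptor genes, Cd300a was 1.80-fold higher on the NKR-P1B+ array (123 against 68.6) and Fcgr3a 1.63-fold higher on the Ly49s3+ array (102 against 62.9), with a list median of 0.16 at the 98.9th percentile. Both probe sets matching 2 Fc gamma receptor genes ran the other way, at 1226 and 2326 on the NKR-P1B+ array against 537 and 1572 on the Ly49s3+ array. The 31 receptor-proximal signalling genes had a median of 0.01, at the 59.7th percentile, with no member 1.5-fold apart.

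Of 34 cytokine genes on the array, 16 were measured and the others were below the floor on both arrays. Of the measured genes 12 were higher on the NKR-P1B+ array, with a median of 0.23 at the 99.8th percentile of random lists. That median fell to 0.056 with the floor at the 35th percentile of all signals and to 0.018 with log2 of the value plus 32, so its size depended on the treatment of low signals. Il4, Tnf and the lymphotoxin gene Ltb (2.31-fold, 2020 against 874) led this group, and Osm was higher on the Ly49s3+ array (87.3 against 58.1). Chemokine receptor, homing and adhesion genes had a median of 0.24 over 22 members, at the 99.99th percentile, which was 0.15 with the lower floor and 0.10 with the added 32. Of them 6 were at least 1.5-fold higher on the NKR-P1B+ array, including Cd93, Ccr2 (at least 2.96-fold, 60.3 against 13.2) and the integrin gene Itgb7 (2.36-fold, 79.9 against 33.8). S1pr1, the receptor that guides lymphocytes out of tissue, was 1.65-fold higher on the Ly49s3+ array (1356 against 821.5), and Ccr10 at least 1.93-fold (39.4 against 11.9). Activation and checkpoint genes had a median of 0.33 over 10 members, at the 99.95th percentile, which was 0.50 with the lower floor, 0.55 with the floor at the 65th percentile and 0.035 with the added 32. The costimulatory receptor gene Icos was 2.60-fold (1207 against 465), Cd83 1.97-fold (1901 against 965) and Cd24 1.80-fold (737 against 408) higher on the NKR-P1B+ array. Tnfsf4, which encodes OX40 ligand, was 2.58-fold higher on the Ly49s3+ array (60.7 against 23.5). With these groups, markers of antigen-presenting cells, macrophages and B cells were also higher on the NKR-P1B+ array, with medians of 0.41, 0.29 and 0.36. Of such markers on the array, 11 of 18, 12 of 31 and 7 of 16 were measured. The first median is the value of Itgax (2281 against 1716), and the last that of Blnk (26.1 against 0.9), a bound. The 27 cytokine receptor and JAK-STAT genes had a median of 0.08 at the 93.4th percentile (0.22 with the lower floor and 0.031 with the higher), and in them Ifngr2 was 2.12-fold higher on the NKR-P1B+ array (47.5 against 22.4). Il6st, the shared receptor chain of the interleukin 6 family, was 2.37-fold higher on the Ly49s3+ array (165.6 against 70.0), with log2 differences from −1.24 to −0.36 over its 3 probe sets.

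Among 31 lymphocyte transcription factors the median was −0.09, at the 2.83rd percentile, with 4 at least 1.5-fold higher on the NKR-P1B+ array and 6 on the Ly49s3+ array. Rora, a nuclear receptor of innate lymphoid cells, was 3.23-fold higher on the NKR-P1B+ array (1252 against 388), Runx1 2.12-fold (92.9 against 43.8) and Maf 1.97-fold (68.4 against 34.7). Id3 was at least 2.07-fold (42.2 against 8.4), Lef1 1.98-fold (169 against 85.3) and Ikzf2 1.82-fold (282 against 155) higher on the Ly49s3+ array. The 16 measured late-maturation NK genes, which are high in mature mouse NK cells, had a median of 0.16 at the 98.9th percentile (0.078 with the added 32), and S100a4 was 3.09-fold higher on the NKR-P1B+ array (323 against 104.7). The 16 early-maturation genes had a median of 0.12 at the 96.3rd percentile (0.046 after quantile normalisation and 0.21 with the lower floor), with members on both sides. Emb, which encodes embigin, was 2.73-fold higher on the NKR-P1B+ array (2717 against 994), as were Tnfsf10 and Ltb, whereas Myb was 1.80-fold (363 against 201.6) and Sox4 1.57-fold (139 against 88.8) higher on the Ly49s3+ array. Another probe set of Sox4 gave a log2 difference of 0.01. The 13 tissue-resident and type 1 innate lymphoid genes had a median of 0.14 at the 96.6th percentile (0.25 with the lower floor), with Rora, Tnfsf10 and Podnl1 (2.18-fold, 68.5 against 31.4) higher on the NKR-P1B+ array and Inpp4b (2.29-fold, 158.6 against 69.3) and Ikzf2 higher on the Ly49s3+ array. Many of these members stand in several lists, 13 of the late-maturation and 14 of the early-maturation genes among them. The markers of antigen-presenting cells, macrophages and B cells given above were higher on the same array as the lists with positive medians here.

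Proliferation genes were lower on the NKR-P1B+ array, with a median of −0.41 over 52 measured members, below all 10000 random lists. The central 95% of random lists lay between −0.13 and 0.08. In this list 19 members were at least 1.5-fold higher on the Ly49s3+ array and none on the NKR-P1B+ array, and 7 were nominally higher on the latter. The mitotic genes Kif2c (at least 2.14-fold, 43.6 against 19.6), Ect2 (2.11-fold, 92.9 against 44.1) and Pbk (1.82-fold, 46.6 against 25.6) had the largest differences, at low signals. Among mast cell and erythroid markers, Mcpt10 and Hemgn were also higher on the Ly49s3+ array, by 2.87-fold (147.6 against 51.5) and 2.59-fold (131 against 50.6). The globin gene Hbb went the other way (276 on the NKR-P1B+ array against 153), as did the probe sets matching 2 globin genes. All 19 cholesterol synthesis genes were lower on the NKR-P1B+ array, with a median of −0.25 at the 0.79th percentile, but only Sqle, which encodes squalene epoxidase, was at least 1.5-fold apart (1.69-fold, 46.5 against 27.5). Immediate early and stress genes went the other way, with a median of 0.27 over 31 members, above all 10000 random lists, and 24 members higher on the NKR-P1B+ array, 6 of them by at least 1.5-fold. Atf3 (2.44-fold, 206 against 84.4), Gadd45a (1.84-fold, 246 against 133.8) and the phosphatase gene Dusp1 (1.74-fold, 1908 against 1096) led it. Interferon-stimulated genes were higher on the NKR-P1B+ array in 33 of 36 members, with a median of 0.20 at the 99.97th percentile, but 32 were within 1.5-fold and 4 were at least 1.5-fold higher. Samhd1, which encodes an enzyme that breaks down deoxynucleotides, was 3.16-fold higher (198 against 62.6), the RNA sensor gene Ifih1 at least 1.77-fold (36.1 against 14.3) and Igtp 1.77-fold (165.6 against 93.7), and the other was Isg15 (1.66-fold, 245 against 148), named after its values were seen. Markers of antigen-presenting cells, macrophages and B cells were higher on the same array as these 2 groups, as given above.

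Other groups differed little on the deposited scale. On the poly-A scale their medians lay from 0.49 to 0.63, near the median of 0.51 over genes above the floor on both arrays. Apoptosis and survival genes had a median of 0.00 over 19 members at the 52.6th percentile, with Bik at least 2.19-fold (44.7 against 10.1) and Bcl2a1 1.64-fold (898 against 549) higher on the NKR-P1B+ array and Bcl2l1 1.52-fold higher on the Ly49s3+ array (109 against 72.0). Glycolysis genes had a median of −0.04 over 18 members at the 35.6th percentile, with Pfkfb3 1.51-fold higher on the NKR-P1B+ array (105 against 69.9). The 20 MHC class I genes had a median of 0.10 at the 95.2nd percentile, with Cd1d1 1.77-fold higher on the NKR-P1B+ array (350.4 against 198). Of 44 cytosolic ribosomal protein genes, with a median of −0.05 at the 5.01st percentile, only Rpl39 was 1.5-fold apart, at 1.88-fold higher on the Ly49s3+ array (147 against 78.3). Of 78 oxidative phosphorylation genes, with a median of 0.04 at the 83.1st percentile, only Ndufaf7 was, at 1.58-fold higher on the Ly49s3+ array (88.5 against 56.0), with log2 differences of −0.66 and −0.089 on its 2 probe sets.

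**Figure D3:**
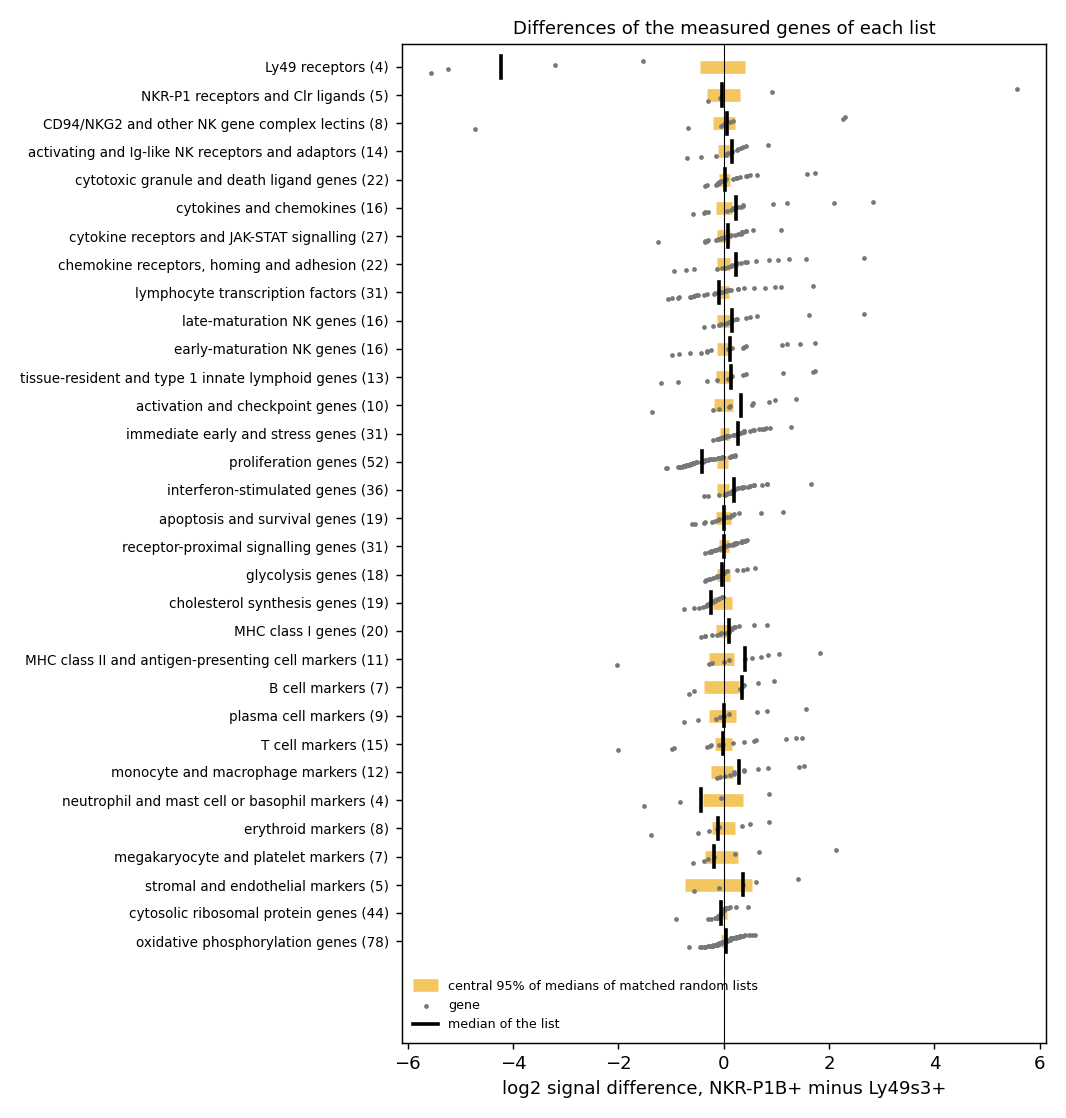
Log2 signal difference (NKR-P1B+ minus Ly49s3+, horizontal) of each measured gene of the 32 lists, 1 list per row with its number of measured genes, the list median as a black bar and the central 95% of medians of matched random lists as a yellow band. The Ly49 median of −4.22 and the proliferation median of −0.41 lay left of their bands on the deposited scale. Scaling to the poly-A spikes would move points with both signals above the floor by 0.53. It would move the proliferation median to 0.017, against 0.51 over genes above the floor on both arrays.

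Markers of other spleen cells were measured because a sort can hold other cells. Antigen-presenting cell markers, with 11 measured, had a median of 0.41 at the 99.98th percentile, which was 0.21 with the floor at the 35th percentile, 0.56 at the 65th, 0.26 without cross-matching probe sets and 0.039 with log2 of the value plus 32. The class II genes RT1-Da (3.54-fold, 346 against 97.7) and RT1-Db1 (at least 2.07-fold, 42.3 against 17.4) and Tcf4 (1.78-fold, 112.5 against 63.1) were higher on the NKR-P1B+ array, Itgax had 2281 and 1716, and Batf3 was at least 4.08-fold higher on the Ly49s3+ array (83.2 against 4.2). Monocyte and macrophage markers had a median of 0.29 over 12 members at the 99.9th percentile (0.16 with the lower floor, 0.71 with the higher and 0.039 with the added 32), with Mpeg1 2.86-fold (78.7 against 27.5), the lysozyme gene Lyz2 2.68-fold (356 against 133) and Cebpb 1.80-fold (99.7 against 55.3) higher on the NKR-P1B+ array and Ctsb at 299 and 312. B cell markers had a median of 0.36 over 7 members at the 98.8th percentile (0.11 with the higher floor and 0.039 with the added 32), with Cd22 1.95-fold (103 against 52.9) and Cd37 1.58-fold (613 against 388) higher on the NKR-P1B+ array and Bank1 1.59-fold higher on the Ly49s3+ array (248 against 156). The antigen-presenting cell median was the value of Itgax, and the B cell median that of Blnk, a bound with low signals. Plasma cell markers had a median of 0.01 over 9 members at the 59.7th percentile. Jchain was 2.94-fold higher on the NKR-P1B+ array (98.1 against 33.4) with log2 differences of 0.12 and 1.55 on its 2 probe sets, Mzb1 at least 1.76-fold (36.0 against 14.1) and Sdc1 1.55-fold (67.5 against 43.6), whereas Fkbp11 was 1.69-fold higher on the Ly49s3+ array (54.4 against 32.1). The brightest plasma cell markers, Xbp1 and Prdm1, had 460 and 455, and 377 and 353.

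T cell markers had a median of −0.01 over 15 members at the 48.5th percentile and a mean of 0.06, and the sign of the median depended on the processing. It was between 0.01 and 0.08 under centring, quantile normalisation and loess, 0.17 without cross-matching probe sets, 0.48 with the floor at the 65th percentile and −0.16 at the 35th. Cd8a, whose product is also carried by rat NK cells, was 2.80-fold higher on the NKR-P1B+ array (2151 against 767), with log2 differences of 1.04 to 1.71 over 3 probe sets, and Icos and Cd5 (2.27-fold, 92.7 against 40.8) were higher there too. CD5 was among the surface proteins used to deplete other cells. Trat1, Lef1 and Cd3g (1.92-fold, 42.9 against 22.3) were higher on the Ly49s3+ array, and the brightest marker, Tcf7, had 2187 and 2734. Neutrophil, mast cell and basophil markers had a median of −0.44 over 4 members at the 1.75th percentile (−0.74 after quantile normalisation and −0.047 with the added 32). Mcpt10 and Mcpt8 (1.78-fold, 38.1 against 21.4) were higher on the Ly49s3+ array and Mmp9 (1.82-fold, 176 against 97.0) on the NKR-P1B+ array. The other markers of the 21 on the array, Fcer1a, Ms4a2 and Hdc among them, were below the floor on both arrays. Erythroid markers had a median of −0.11 over 8 members at the 19.0th percentile. Hbb, a globin gene, was 1.81-fold higher on the NKR-P1B+ array (276 against 153), as were all 5 probe sets matching 2 globin genes, the brightest at 724 against 333, while Tfrc had 537 and 589. Platelet markers had a median of −0.19 over 7 members at the 16.7th percentile and a mean of 0.22, with Itgb3 and Nrgn (1.59-fold, 86.0 against 54.2) higher on the NKR-P1B+ array and Rgs18 at 204 and 251.5. Stromal and endothelial markers had a median of 0.36 over 5 members at the 93.2nd percentile, with Kdr at least 2.65-fold (54.1 against 11.8) and Tie1 1.52-fold (33.5 against 22) higher on the NKR-P1B+ array and Acta2 at 33.5 and 49.8. The medians of these last 2 lists changed sign with the floor.

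Probe sets with no listed gene or several genes also differed, 66 of 4295 measured being at least 2-fold higher on the NKR-P1B+ array and 61 on the Ly49s3+ array. The largest unnamed differences were those of a probe set 17.4-fold higher on the Ly49s3+ array (818 against 47.1), and of a probe set 8.13-fold higher on the NKR-P1B+ array (524.5 against 64.5).

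The spread between probe sets of the same gene, as the SD of the log2 difference for a single probe set, was 0.38 at mean signals from 20.4 to 50, 0.25 from 100 to 200 and 0.17 from 500. This spread holds no variation between rats, sorts or arrays. Where a gene at least 2-fold apart had another probe set above the floor on both arrays, that probe set went the same way in 23 of 27 genes, and by at least 1.5-fold in 18. Spiked hybridisation controls had a median log2 difference of 0.01 over 18 probe sets. Poly-A spikes, which are commonly added to the RNA before labelling, had −0.53 over 17, 16 of them lower on the NKR-P1B+ array. The poly-A differences ran from −0.97 to 0.21, with an SD of 0.31. Whether equal amounts were added to both samples is not given in the sources used here. Scaling to the poly-A spikes would raise each NKR-P1B+ signal by 0.53 on the log2 scale before the floor is applied, and give 713 genes at least 2-fold higher on the NKR-P1B+ array and 35 on the Ly49s3+ array. All list directions, medians and counts of members apart here are therefore relative to the deposited scale. On the poly-A scale the only list medians below 0 were those of the Ly49 genes, at −4.04, and of the neutrophil, mast cell and basophil markers, at −0.17.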

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

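The floor at 100, the poly-A scale, the lists of members with a mean signal of at least 100 and the inclusion of Ly49 probe sets of several genes were chosen after seeing the data, and the others before. No paired analysis was possible because there is 1 array per population and no test. Against 162 genes at least 2-fold higher on the NKR-P1B+ array and 110 on the Ly49s3+ array, the counts were 274 and 298 with the floor at the 35th percentile, 86 and 43 at the 65th, 54 and 23 at a signal of 100, and 77 and 37 with log2 of the value plus 32. A 1.5-fold threshold gave 466 and 522 and a 3-fold threshold 41 and 23, by their construction. Scaling to the poly-A spikes gave 713 and 35, since it raises the NKR-P1B+ signals by 0.53 before the floor is applied. It moved the proliferation median from −0.41 to 0.017, still below the 0.51 over genes above the floor on both arrays. Centring, quantile normalisation, loess, the mean over probe sets and leaving out cross-matching probe sets kept each count within 1.5 times, and under no setting fixed beforehand did a counted gene become 2-fold apart in the opposite direction. The Ly49 median of −4.22 was −4.58 with the floor at the 35th percentile, −2.85 at the 65th, and −3.13 with log2 of the value plus 32, and the Klrb1b difference of 5.57 was 4.73 at the 65th percentile and 4.54 with the added 32, because the lower signal lies near or below the floor. With the probe sets of several genes the Ly49 median was −4.83. With the floor at the 35th percentile the medians were 0.056 for cytokines, 0.22 for cytokine receptors, 0.15 for homing, 0.21 for early-maturation, 0.25 for tissue-resident, 0.50 for activation and −0.51 for proliferation genes. At the 65th percentile they were 0.33 for cytokines and 0.55 for activation genes. With log2 of the value plus 32 they were 0.018 for cytokines, 0.10 for homing, 0.078 for late-maturation and 0.035 for activation genes. Quantile normalisation gave 0.046 for early-maturation and 0.22 for immediate early genes. The proliferation median was −0.51 without cross-matching probe sets and −0.54 over members with a mean signal of at least 100. The median of platelet markers turned from −0.19 to 0.67 with the floor at the 65th percentile and to 0.0041 with the added 32, and that of stromal markers from 0.36 to −0.089 at the 35th percentile and to −0.011 with the added 32. The T cell median of −0.01 was −0.16 at the 35th percentile, 0.48 at the 65th and 0.17 without cross-matching probe sets. At the 35th and 65th percentiles and with the added 32, the antigen-presenting cell median of 0.41 was 0.21, 0.56 and 0.039, and the macrophage median of 0.29 was 0.16, 0.71 and 0.039. The B cell median of 0.36 was 0.11 at the 65th percentile and 0.039 with the added 32. The cause of these list changes was not tested. No named gene at least 1.5-fold apart changed sign under a setting fixed beforehand that gave it a value, but of 121 named genes 15 had none with the floor at the 65th percentile and 8 none without cross-matching probe sets. By more than the spread between probe sets, 15 named genes moved with the floor at the 35th percentile and 32 at the 65th. With the added 32 it was 53 and with the mean over probe sets 8. Signals near the floor limit the results, as 62 of the 162 genes and 56 of the 110 had a mean signal below 50.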

Other observations

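The 7 gene families described next and all tests of explanations in this part were chosen after the differences had been seen, so the family medians partly restate the genes that prompted them. Markers of antigen-presenting cells, macrophages and B cells, with medians of 0.41, 0.29 and 0.36, were higher on the same array as the families with positive medians. Genes of the TNF and TNF receptor superfamily, which carry death and costimulatory signals, had a median log2 difference of 0.39 over 18 measured members, NKR-P1B+ minus Ly49s3+. At least 1.5-fold higher on the NKR-P1B+ array were 5 of them, Tnfrsf25, Tnf, Tnfsf10, Faslg and Ltb, all of which except Tnfrsf25 also stand in lists described before, and 3 were higher on the Ly49s3+ array, Tnfsf4, Tnfrsf26 (584 against 352) and Tnfrsf21 (at least 1.72-fold, 35.1 against 19.7). Among 10 feedback regulators of the ERK pathway the median was 0.35, lying between the values of Dusp5 and Dusp2. Dusp1, Dusp2 and Dusp5 also stand in the immediate early list. The Sprouty genes were split. Spry1 was 3.36-fold (181 against 53.8) and the phosphatase gene Dusp6 3.39-fold (91.6 against 27.0) higher on the NKR-P1B+ array, whereas Spry2 was 1.90-fold (1987 against 1048) and Spry4 1.60-fold (114.6 against 71.8) higher on the Ly49s3+ array. All medians in this part are relative to the deposited scale, and on the poly-A scale only that of the mast cell proteases, at −0.35, was below 0 among these families.

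Regulators of G protein signalling had a median of −0.21 over 10 members, with Rgs16, Rgs10 (1.91-fold, 399 against 209) and Rgs12 (at least 2.06-fold, 42.0 against 18.8, its other probe set going the opposite way) higher on the Ly49s3+ array, while Rgs1 had 4647 on the NKR-P1B+ array and 3469 on the Ly49s3+ array. Mast cell protease genes had a median of −0.88 over 4 members, Mcpt8, Mcpt9, Mcpt10 and Tpsb2. The Mcpt genes are similar enough to share signal, and Mcpt8 and Tpsb2 lay at or near the floor on the NKR-P1B+ array. Mcpt9 was 1.91-fold higher on the Ly49s3+ array (638 against 335), and a probe set matching 4 such genes had 1521 there against 945. S100 genes had a median of 0.30 over 6 members, with S100a4 and S100a11 (2.48-fold, 224 against 90.3) higher on the NKR-P1B+ array. Mitochondrial solute carriers had a median of −0.09 over 33 members, with Slc25a4, the serine carrier gene Sfxn1 (2.59-fold, 501 against 193) and Slc25a10 (at least 1.94-fold, 39.5 against 20.2) higher on the Ly49s3+ array. The other probe set of Slc25a10 gave a log2 difference of −0.14. Slc25a25 (1.88-fold, 167 against 88.7) and Slc25a45 (at least 1.93-fold, 39.4 against 19.3) were higher on the NKR-P1B+ array. The 17 aminoacyl-tRNA synthetase genes had a median of −0.10 and no member 1.5-fold apart.

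Proliferation genes were lower on the NKR-P1B+ array, with a median of −0.41 over 52 genes. A bias of low signals between the arrays would spare the brighter members, but the 24 members with a mean signal of at least 100 had a median of −0.54 with an SD of 0.32, and the whole list had −0.38 after a loess trend with signal was subtracted. Cycling precursors of red cells in the Ly49s3+ sort would raise the globin transcripts on that array, but all 6 globin probe sets above the floor on both arrays were lower there, with a median log2 difference of 1.05 and an SD of 0.36. The precursor genes Alas2 (17.2 on the NKR-P1B+ array and 2.3 on the Ly49s3+ array), Ahsp (2.5 and 8.0), Klf1 (1.5 and 1.5) and Gata1 (5.8 and 8.0) were below the floor on both arrays. On the other side, Hemgn was higher on the Ly49s3+ array. The brighter members and the loess result argue against a bias of low signals as the whole source. The globin values cannot decide on red cell precursors, because globin RNA of other red cells in the NKR-P1B+ sort could mask them. Other cycling cells were not tested. A difference in cell division between the 2 NK populations stays an open, untested explanation. On the poly-A scale the proliferation median was 0.017, below the 0.51 over genes above the floor on both arrays.

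Cd8a, Icos, Cd5 and Cd6 were higher on the NKR-P1B+ array, Cd6 (273 against 179) being added to this group after its values were seen. T cells left in that sort would raise T cell markers in general, but all 15 measured markers, these 4 among them, had a median of −0.014 with an SD of 0.94 and went both ways, 7 of them higher. The median was 0.38 over members with a mean signal of at least 100 and 0.48 with the floor at the 65th percentile. Cd3g was lower on the NKR-P1B+ array (22.3 against 42.9), and Cd3e (0.7 and 0.9) and Cd3d (1.7 and 19.4) were below the floor on both arrays, which alone excludes no T cells. The sort took CD3-negative cells after depletion with antibodies to CD5 and the alpha-beta T cell receptor, and 8 of the 15 markers stand in other lists of lymphocyte genes. T cells therefore cannot be told apart from expression by the NK cells themselves, because the markers move apart and those of CD3 lie near or below the floor.

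RT1-Da, Cd74 (1.64-fold, 197 against 120), Lyz2, Mpeg1 and the globin genes were higher on the NKR-P1B+ array, Cd74 and the class II genes that follow being named after their values were seen. RT1-DMb had 96.8 and 96.2, and RT1-Ba (30.2 and 36.7) and RT1-DMa (26.3 and 30.6) were nominally lower on the NKR-P1B+ array. Cd68, Csf1r, C1qa, Ms4a1 and Cd79b were below the floor on both arrays, and the cells had been depleted with antibodies to CD68, CD45RA and immunoglobulin kappa. No test independent of these genes was made here, so RNA of other cells in the sort and transcripts of the NK cells themselves both stay open and untested.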
